A study of Homo sapiens with 9 samples.

How the data were processed

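RNA of MCF10A cells was measured on Affymetrix whole-transcript arrays, with 3 arrays for each of 3 groups (control, WT-HER2 and Delta-HER2) and 9 arrays in all. The labels do not state whether the replicates of a group were separate cultures, so p-values here measure the spread between these samples. The deposited values are on the log2 scale and were made by the authors, per the submitters' processing notes, with RMA from the affy package in R 2.14, which corrects for background, normalizes by quantiles and summarises probes per transcript cluster. No genome build is stated, and no coordinates were used. The table held 32321 transcript clusters (called probes here), array medians were alike, and the largest gap between sorted arrays at any rank was 0.23 log2, as quantile normalization at the probe level leaves it. Values were used as deposited.

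Probes were named from the annotation of the array. Of them, 19158 had exactly 1 gene symbol, 1388 had several and 11775 were not listed. Entrez gene numbers were matched for 19128 of those with 1 symbol and not for 30. Each gene was represented by the probe with the highest mean over all arrays (637 genes had several probes), which gave 18404 genes. No filter on low values was applied. The level of 340 olfactory receptor genes, which are expressed mainly in olfactory neurons, served as a gauge of background, and its 0.95 quantile of 3.18 as a bound; differences from or to a level under it are uncertain in size. Values counted as equal were identical as deposited. Probes without a single symbol were left out of the comparisons because no gene could be named for them, and their counts are given with the additional observations.

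Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 coefficient per group, all 9 arrays in the fit and moderated statistics (residual degrees of freedom 6, prior 3.25). The contrasts were WT-HER2 against control, Delta-HER2 against control and Delta-HER2 against WT-HER2, and an F test covered all groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 18404 genes of a contrast, and a gene was called at adjusted p below 0.05. The replicate numbers were not used as a block, since only 1 of the 9 arrays correlated best with arrays of its own number. The median SE of a difference was 0.10 log2, which sets the precision.

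Changes of gene groups were tested with camera, with a preset correlation of 0.01, on 32 lists of genes, adjusted over the lists within each contrast. Camera with an estimated correlation and fry were run beside it. Overlap of the responses was compared with the product of the call rates and with 100 simulations of unchanged groups that share their controls. The comparisons, tests, gene lists and alternatives were chosen before the data were examined, save those named as later additions. Genes are named by a rule set at the same time. It takes ERBB2 and the other ERBB receptors, for each contrast the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, and for each list and contrast up to 4 members with the smallest p. Counts of 5 or fewer could be named in full, which added the single members that went against the rest of their list (SAMD9 with WT-HER2, EPHA4, TRIB2 and SREBF1 with Delta-HER2) and E2F1, the single DNA replication gene that did not pass with Delta-HER2, and genes in opposite directions were picked for mention after their values were seen.

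The procedure was tested on simulated data with 200 changed genes among 18404, in 20 runs. Each gene had the spread from the fit of all 9 arrays, the same for both comparisons. For WT-HER2 against control 56.9% of genes changed by 0.5 log2 were recovered, with 5.66% of calls false. The shares were 97.8% for genes changed by 1 log2 and 99.9% for those changed by 2. For Delta-HER2 against control they were 57.6%, 97.4% and 100%, with 5.14% false. When mitosis genes were shifted by 0.5 log2 the list was called in 20 of 20 runs with either correlation, and 0.15 of the 31 other lists were called per run on average. Genes were drawn independently of each other, so these runs do not show how often lists of correlated genes are called falsely. All arrays were drawn with the same spread, whereas weights estimated for the real arrays ranged from 0.246 to 2.094. The shares of recovered and false calls may therefore differ in the real data. The alternatives were quantile normalization and median centring of the table, filters on low values, all probes, the mean of a gene's probes, trended and robust variance estimates, array weights, the replicate number as a block, pairs of groups fitted alone, stricter thresholds, other list tests and each array left out in turn. Leaving out 2 or 3 arrays together and a covariate from the olfactory receptor genes were added after the arrays had been seen.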

Results

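Gene expression was measured in MCF10A, an established, non-tumorigenic human mammary epithelial line that is grown with added epidermal growth factor. Per the labels, 3 arrays came from control cells, 3 from cells expressing wild-type HER2 (WT-HER2) and 3 from cells expressing Delta-HER2, a splice variant of the receptor tyrosine kinase that the gene ERBB2 encodes. The control cells are called parental in one label and empty-vector cells in the description of the design. The growth medium of all cells held 5% horse serum and 20 ng/ml epidermal growth factor. Before RNA was taken, all cells spent 16 hours in serum-free medium, for which antibiotics are the one supplement named. Each whole-transcript array gave 32321 values on the log2 scale, with array medians from 4.04 to 4.18. Every group had n = 3 arrays, and that number limits the precision; the median standard error (SE) of a difference was 0.10 log2.

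The main axis of variation between arrays, with 64.9% of the variance, set the 3 Delta-HER2 arrays (scores 38.67 to 41.66) apart from the other arrays (scores −23.98 to −15.53). The next axis, with 16.6%, set WT-HER2 replicate 3 (32.07) and control replicate 1 (10.34) apart from the other arrays of their own groups. Across genes, which are not independent replicates, the deviations of these 2 arrays from their group means correlated at r = 0.64. As a gauge of background, 340 olfactory receptor genes had a median level of 2.41 and an upper bound, the 0.95 quantile, of 3.18; all 3 group means of 4733 of the 18404 genes tested lay under that bound.

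The level of ERBB2 (probe 8006906, Entrez gene 2064) differed in steps between the groups. It was 6.99 ± 0.10 (SD, n = 3) in control cells, 7.98 with WT-HER2 and 8.95 ± 0.02 with Delta-HER2. Thus ERBB2 rose 1.98-fold with WT-HER2 (log2 difference 0.99, SE 0.07, adjusted p = 1.99e-04) and 3.89-fold with Delta-HER2 (1.96, SE 0.07, adjusted p = 1.82e-07). Between the HER2 lines the difference was 1.97-fold (0.98, adjusted p = 8.57e-06), so the measured ERBB2 level differed between the lines. The 3 WT-HER2 values were identical in the table (SD 0.000), as were those of 465 probes in all, and that SD is not taken as a measure of precision. The identical values do enter the spread shared by the groups, so the SE and p-values of ERBB2 may be too small. The probe reports a summary of the signal over the gene, not a sum, and does not tell the splice variant from the full-length transcript.

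The partner receptors went the other way in Delta-HER2 cells. ERBB3, a kinase-impaired partner of HER2, had levels of 6.36 ± 0.10 in control, 6.06 ± 0.05 in WT-HER2 and 5.22 ± 0.02 in Delta-HER2 cells (SD), and fell by 1.14 log2 with Delta-HER2 (SE 0.07, adjusted p = 3.60e-06). EGFR, the receptor of epidermal growth factor, fell by 0.46 log2 with Delta-HER2 (SE 0.08, adjusted p = 0.00280). Neither passed the test over all genes with WT-HER2, where the differences were −0.30 for ERBB3 (adjusted p = 0.0902) and −0.16 for EGFR (adjusted p = 0.537). Adjusted over the 4 ERBB receptors alone, ERBB3 was lower with WT-HER2 too. ERBB4 lay at the level of the olfactory receptor genes in all groups (2.73, 2.74 and 2.72).

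**Figure D1:**
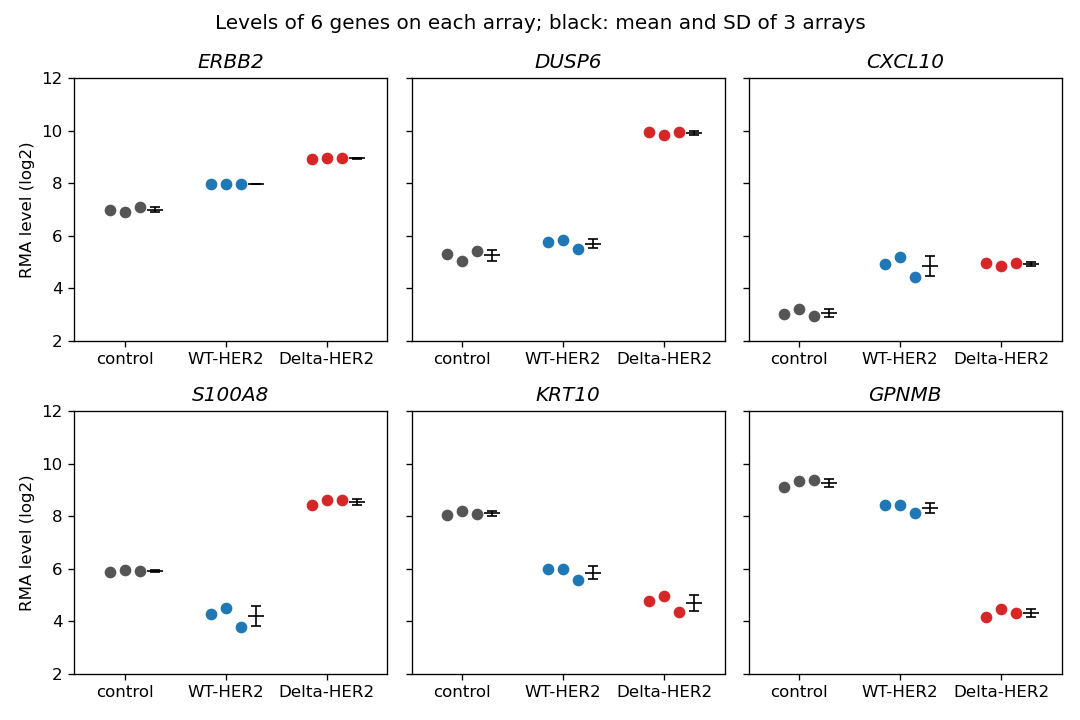
RMA level (log2) of 6 genes on each array, with colored points for the 3 arrays of each group and black bars for the mean and SD. ERBB2 stood at 6.99, 7.98 and 8.95 in control, WT-HER2 and Delta-HER2 cells, while DUSP6 was at 9.92 in Delta-HER2 and at 5.70 in WT-HER2 cells.

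The comparison of WT-HER2 with control cells asks how expression differed in cells with the full-length receptor. In this design, effects of making a HER2 line cannot be told apart from those of its receptor. Of 26 genes of squamous differentiation 11 were lower, and of 27 interferon response genes 11 were higher, although the interferon list did not pass with an estimated correlation (adjusted p = 0.0586). OASL, a member of the interferon-induced oligoadenylate synthetase family, rose 2.75-fold (log2 difference 1.46, SE 0.10, adjusted p = 1.99e-04). The chemokine gene CXCL10 rose by 1.79 log2 (SE 0.17, adjusted p = 0.00104), from a control level of 3.05 within the background range, which leaves the size of the change uncertain. KRT10, a keratin of differentiating keratinocytes, fell by 2.26 log2 (SE 0.16, adjusted p = 2.62e-04), from 8.11 ± 0.08 to 5.85 ± 0.24 (SD).

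Of 27 interferon response genes measured, 11 rose and 1 fell in WT-HER2 cells, and adjusted over the list alone 17 were higher and 1 was lower. The median difference was 0.46, and the list passed camera with adjusted p = 2.53e-18, though with adjusted p = 0.0586 with an estimated correlation. The members that rose most after OASL were IFI44L (1.36), RSAD2 (1.27), IFIT1 (1.25) and IFIT3 (1.22), antiviral effectors induced by interferon, of which IFIT3 had adjusted p = 0.00155. Single arrays decided some of these calls. IFI44L did not pass without control replicate 2 (adjusted p = 0.0570), WT-HER2 replicate 1 (0.0546) or WT-HER2 replicate 2 (0.0543), and IFIT1 did not without control replicate 2 (0.0582) or WT-HER2 replicate 2 (0.0587). RSAD2 did not pass without control replicate 1, 2 or 3 or WT-HER2 replicate 1 or 2 (adjusted p from 0.0601 to 0.0873). The gene that fell was SAMD9 (−0.71, adjusted p = 0.0355).

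Genes of squamous differentiation and keratinisation fell in WT-HER2 cells, with 11 of 26 lower and 0 higher over all genes, and with 16 lower and 1 higher adjusted over the list alone. The list's median was −0.46 (camera adjusted p = 9.70e-15, and adjusted p = 0.0241 with an estimated correlation). Beside KRT10, the protease inhibitor gene PI3 fell by 1.96 log2 (SE 0.11), the stress keratin gene KRT16 by 1.29 (SE 0.10) and S100A8, which encodes a subunit of calprotectin, by 1.71 (SE 0.16).

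Genes of ERK pathway output, which ERK signaling induces and several of which restrain it, were higher. With WT-HER2, 6 of 20 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 8.11e-08, and adjusted p = 0.0241 with an estimated correlation). The phosphatase gene DUSP4 rose by 1.10 (adjusted p = 7.60e-04) and EPHA2, an ephrin receptor gene, by 0.59 (adjusted p = 0.00600), while EPHA4, another ephrin receptor gene, fell by 1.87 (SE 0.12, adjusted p = 1.99e-04). Of 25 mesenchymal genes, 7 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 5.27e-08, and adjusted p = 0.0241 with an estimated correlation). Those with the smallest p were matrix and adhesion genes. They were the type IV collagen genes COL4A2 (0.78, SE 0.07) and COL4A1 (0.57, SE 0.08), LOX, which encodes a collagen cross-linking enzyme (1.07, SE 0.11), and the integrin gene ITGA5 (0.62, SE 0.07).

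In WT-HER2 cells 10 further lists passed camera, each of which was lost with an estimated correlation. Among 18 NRF2 targets 2 rose (5 adjusted over the list alone; adjusted p = 0.230 with an estimated correlation). No mitosis gene of 24 passed over all genes (median 0.14, 1 higher adjusted over the list alone), and the list's preset-correlation call (adjusted p = 1.63e-04) stood at adjusted p = 0.347 with an estimated correlation. Of the DNA replication genes, 2 of 25 rose (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). Of 26 NF-kB targets and cytokines 3 rose (4 adjusted over the list alone), among them SOD2, the mitochondrial superoxide dismutase gene, by 0.78 (adjusted p = 0.0957 with an estimated correlation for the list). Among basement membrane and collagen genes 3 of 22 rose (4 adjusted over the list alone; adjusted p = 0.0957 with an estimated correlation), and COL4A1 and COL4A2 were among these. Of the unfolded protein and amino acid stress genes, 3 of 22 rose (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.120 with an estimated correlation), and PHGDH, a serine synthesis gene, led with 0.78. In the hypoxia response list 3 of 19 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation).

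Among the lists with lower values in WT-HER2 cells, 3 of 23 epithelial junction and identity genes fell (7 adjusted over the list alone; adjusted p = 0.120 with an estimated correlation). Of 15 basal and myoepithelial markers 3 fell and 2 rose (6 and 3 adjusted over the list alone; adjusted p = 0.120 with an estimated correlation), and the enzyme gene MME (−0.93, SE 0.09) and the basal keratin gene KRT14 (−0.68, SE 0.08) were among those that fell. None of 11 histone genes passed over all genes, and 3 were lower adjusted over the list alone (median −0.21; adjusted p = 0.165 with an estimated correlation), while among 69 histone genes of all families, a set chosen after the values were seen, 1 was higher and 0 were lower (median −0.002). Several of these weaker list calls hung on single arrays. The DNA replication call was lost without control replicate 1 (adjusted p = 0.122), those of NF-kB targets (0.0651) and basal markers (0.0661) without WT-HER2 replicate 2, and that of the stress response list without control replicate 1 (0.177) or WT-HER2 replicate 2 (0.0524). The hypoxia list did not pass without control replicate 1, WT-HER2 replicate 1 or 2, or Delta-HER2 replicate 1 or 3 (adjusted p from 0.0525 to 0.156).

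The largest differences outside these groups were increases of CPM, a membrane carboxypeptidase gene (1.72, SE 0.15), DEPP1 (1.36, SE 0.10), the proteoglycan gene VCAN (1.26, SE 0.16) and the receptor gene GPR141 (1.16, SE 0.12). The decreases were those of the small heat shock protein gene CRYAB (−2.10, SE 0.12), the ubiquitin-like gene UBD (−2.07, SE 0.30), C1orf74 (−1.82, SE 0.12), the synaptotagmin gene SYT14 (−1.60, SE 0.17), the carbonic anhydrase gene CA2 (−1.53, SE 0.10) and IGFBP5, which encodes a binder of insulin-like growth factors (−1.49, SE 0.10). UBD did not pass without control replicate 2 (adjusted p = 0.0519), control replicate 3 (0.0576) or WT-HER2 replicate 2 (0.0527). In all, 309 of 18404 genes (1.68%) passed limma at adjusted p below 0.05, 143 higher and 166 lower, and 47 of them differed at least 2-fold. Which direction had more genes turned with quantile normalization (192 higher and 179 lower), with the olfactory receptor covariate (307 and 299), without WT-HER2 replicate 3 (135 and 101) and without control replicate 3 (66 and 60). The 3 arrays of each group did not overlap for 2582 genes, or 14.0%, against 10% by chance. The count of 309 called genes was 129 or 126 without control replicate 2 or 3, and 155 or 152 without WT-HER2 replicate 1 or 2. It was 736 with array weights, 606 with the olfactory receptor covariate and 134 with only the 2 groups in the fit. The other 18 lists did not pass, with camera adjusted p from 0.0508 for FOXO targets to 0.985 for fibroblast markers. Marker lists of cell types other than epithelium did not pass either (fibroblast median 0.06, blood and immune 0.07, endothelial 0.02, the latter with camera adjusted p = 0.908). Median, mean and test differed in sign for the ERBB receptors, EGF-family ligands, immediate-early genes, fatty acid synthesis, p53 targets and fibroblast markers.

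The comparison of Delta-HER2 with control cells asks how expression differed in cells with the splice variant. Genes of ERK pathway output, DNA replication, mitosis, sterol and fatty acid synthesis and glycolysis were higher, and FOXO targets were lower. DUSP6, a phosphatase gene that ERK signaling induces and whose product inactivates ERK, rose 25.45-fold, from 5.25 ± 0.20 to 9.92 ± 0.07 (SD; log2 difference 4.67, SE 0.12, adjusted p = 7.30e-08). GPNMB, which encodes a membrane glycoprotein of lysosomes and melanosomes, fell by 4.97 log2, from 9.28 ± 0.15 to 4.31 ± 0.14 (SE 0.12, adjusted p = 7.30e-08).

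With Delta-HER2, 16 of 20 genes of ERK pathway output rose and 1 fell, over all genes and adjusted over the list alone, with a median of 1.78 (camera adjusted p = 9.05e-16, and adjusted p = 0.0101 with an estimated correlation). Beside DUSP6, the ETS transcription factor genes ETV5 and ETV1 rose by 3.67 (SE 0.10) and 3.03 (SE 0.08) from background levels, SPRY4, a feedback inhibitor gene, by 3.87 (SE 0.14) and PHLDA1 by 2.73 (SE 0.09). The member that fell was EPHA4 (−2.59, adjusted p = 7.28e-07). Among 10 EGF-family ligands 3 rose and 2 fell, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.192). The ligand genes EREG (3.36, SE 0.15), HBEGF (2.74, SE 0.12) and TGFA (1.19, SE 0.09) rose, and NRG2 fell by 0.67 (SE 0.08). Of 18 immediate-early genes 6 rose and 1 fell, over all genes and adjusted over the list alone, and that list did not pass (camera adjusted p = 0.127). FOS rose 3.57-fold and EGR1 2.83-fold, and KLF4 fell by 1.99 log2.

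Of 21 FOXO targets, genes that FOXO factors induce when AKT signaling is low, 18 fell and 1 rose, over all genes and adjusted over the list alone. Their median was −0.68 (camera adjusted p = 4.74e-12, and adjusted p = 0.0178 with an estimated correlation). PDK4, which encodes a kinase that blocks pyruvate oxidation, fell by 2.88 (SE 0.09, adjusted p = 1.26e-07), the ubiquitin ligase adaptor gene KLHL24 by 1.80 (SE 0.11) and PIK3IP1, whose product inhibits PI3-kinase, by 1.74 (SE 0.09). The member that rose was TRIB2 (1.58, adjusted p = 5.34e-06).

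All 24 mitosis genes measured rose with Delta-HER2, over all genes and adjusted over the list alone, with a median of 1.54 (camera adjusted p = 1.01e-22, and adjusted p = 0.0385 with an estimated correlation). The proliferation marker MKI67 rose 2.90-fold (SE 0.07 log2), the mitotic cyclin gene CCNB1 2.98-fold and the checkpoint kinase gene BUB1B 3.95-fold. Of 25 DNA replication genes 24 rose, over all genes and adjusted over the list alone, with a median of 1.96 (camera adjusted p = 5.38e-24, and adjusted p = 0.0120 with an estimated correlation). Among them were genes of the replicative helicase, with MCM6 7.25-fold (SE 0.11 log2), CDC45 6.56-fold (SE 0.09) and MCM5 4.26-fold (SE 0.07) higher. The member that did not pass was the transcription factor gene E2F1 (0.18, adjusted p = 0.382).

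Metabolic genes rose in 3 groups. Of 16 genes of cholesterol synthesis and uptake 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 4.74e-12, and adjusted p = 0.0178 with an estimated correlation). HMGCS1, which acts early in sterol synthesis, rose by 1.80 (SE 0.10) and INSIG1, a sterol-regulated feedback gene, by 1.33 (SE 0.07). Of 12 fatty acid synthesis genes 8 rose and 1, SREBF1, fell (9 and 1 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 4.49e-06, and adjusted p = 0.0286 with an estimated correlation). The citrate lyase gene ACLY rose by 1.31 (SE 0.06) and the desaturase gene FADS2 by 1.48 (SE 0.07). Of 18 glycolysis genes 15 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.80 (camera adjusted p = 7.96e-11, and adjusted p = 0.0178 with an estimated correlation). PGK1 rose by 1.28 (SE 0.07) and TPI1 by 1.21 (SE 0.08), while the glucose transporter genes moved apart: SLC2A3 rose by 2.28 (SE 0.09) from a background level and SLC2A1 fell by 0.95 (SE 0.06).

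Of 26 NF-kB targets and cytokines 10 rose and 0 fell with Delta-HER2 (12 and 0 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 2.93e-04, and adjusted p = 0.0261 with an estimated correlation). The interleukin genes IL1A (2.12, SE 0.17), CXCL8 (2.10, SE 0.15) and IL1B (1.88, SE 0.11) rose. Interferon response genes did not pass as a list in Delta-HER2 cells (median 0.10, camera adjusted p = 0.303), with 5 of 27 higher and 2 lower, over all genes and adjusted over the list alone. Over all genes these counts were 10 and 3 with the olfactory receptor covariate and 5 and 5 with control replicate 1 and WT-HER2 replicate 3 left out. OASL rose by 1.39 and RIGI, an RNA sensor gene, by 1.27, while IRF9, a subunit of the interferon-activated ISGF3 complex, fell by 0.35.

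Squamous differentiation genes split in Delta-HER2 cells. Of 26, 12 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of −0.48 (camera adjusted p = 3.13e-05, but adjusted p = 0.0766 with an estimated correlation). KRT10 fell by 3.40 (SE 0.16), the desmosomal cadherin genes DSC2 by 1.74 (SE 0.09) and DSG3 by 1.71 (SE 0.08), and the members that rose were the calprotectin genes S100A8 (2.66, SE 0.16) and S100A9 (2.21, SE 0.16). Of 23 epithelial junction and identity genes 7 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0766 with an estimated correlation), and 13 fell with the olfactory receptor covariate. The claudin gene CLDN7 fell by 1.41 (SE 0.07) and CDH1, which encodes E-cadherin, by 1.03 (SE 0.07). Of 25 mesenchymal genes 11 rose and 4 fell (14 and 5 adjusted over the list alone; adjusted p = 0.0766 with an estimated correlation), among them ITGA5 (1.46, SE 0.07) and CDH2, which encodes N-cadherin (1.29, SE 0.08), while TGFBI fell by 0.86. Of 15 basal and myoepithelial markers 4 fell and 2 rose (5 and 2 adjusted over the list alone; adjusted p = 0.0943 with an estimated correlation), and KRT15 fell most (−1.81, SE 0.09). The luminal list did not pass (camera adjusted p = 0.549), with 3 of 21 higher and 3 lower, over all genes and adjusted over the list alone. The luminal transcription factor genes ELF3 (−2.40, SE 0.09) and GATA3 (−1.02, SE 0.09) and the mucin gene MUC1 (−1.01) fell, and XBP1, a secretory cell transcription factor gene (0.81), was among those that rose.

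A further 5 lists passed camera in Delta-HER2 cells and were lost with an estimated correlation. Of 19 hypoxia response genes 10 rose and 3 fell, over all genes and adjusted over the list alone (adjusted p = 0.216 with an estimated correlation), with the angiogenic factor gene VEGFA 3.92-fold higher and the peptide hormone gene ADM 2.49-fold lower. Of 13 integrins 8 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation). Among the unfolded protein and amino acid stress genes 9 of 22 rose and 5 fell (12 and 5 adjusted over the list alone; adjusted p = 0.0943 with an estimated correlation), and PSAT1, of serine synthesis, rose 3.17-fold. Of 19 p53 targets 9 fell and 2 rose (10 and 3 adjusted over the list alone; adjusted p = 0.224 with an estimated correlation), with TP53INP1 3.89-fold lower. Of 25 ribosomal protein genes 6 fell and 0 rose, over all genes and adjusted over the list alone (median −0.21; adjusted p = 0.272 with an estimated correlation), and 10 fell with the olfactory receptor covariate.

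Beyond the groups, SERPINE2, a secreted protease inhibitor gene, rose 24.00-fold in Delta-HER2 cells, from 3.61 ± 0.27 to 8.20 ± 0.12 (SD; adjusted p = 7.41e-08). The other large increases were those of DTL, a ubiquitin ligase subunit gene of the S phase (4.29, SE 0.16), VCAN (3.79, SE 0.16), the secreted glycoprotein gene STC1 (3.64, SE 0.10), FAM111B (3.43, SE 0.15, from a background level) and the histone gene H2BC14 (3.40, SE 0.22). The drug-metabolising cytochrome gene CYP3A4 fell by 4.77 (SE 0.23), to a level within the background range. The other large decreases were those of SYT14 (−3.22, SE 0.17), the non-coding genes LCAL1 (−3.14, SE 0.27) and LINC00417 (−2.84, SE 0.11), the mechanosensitive channel gene PIEZO2 (−2.88, SE 0.19), CD24, a cell surface marker gene (−2.84, SE 0.24), and the selenoprotein gene SELENOP (−2.82, SE 0.20). In all, 4669 of 18404 genes (25.4%) passed limma, 2509 higher and 2160 lower, and 961 of them differed at least 2-fold. The 3 arrays of each group did not overlap for 6814 genes (37.0%, against 10% by chance). The other 15 lists did not pass, with camera adjusted p from 0.127 to 0.862, and fibroblast (median −0.01), blood and immune (−0.03) and endothelial markers (−0.02) were among them. Median, mean and test differed in sign for the ERBB receptors, YAP targets, basement membrane and collagen genes, BCL2 family and endothelial markers.

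**Figure D2:**
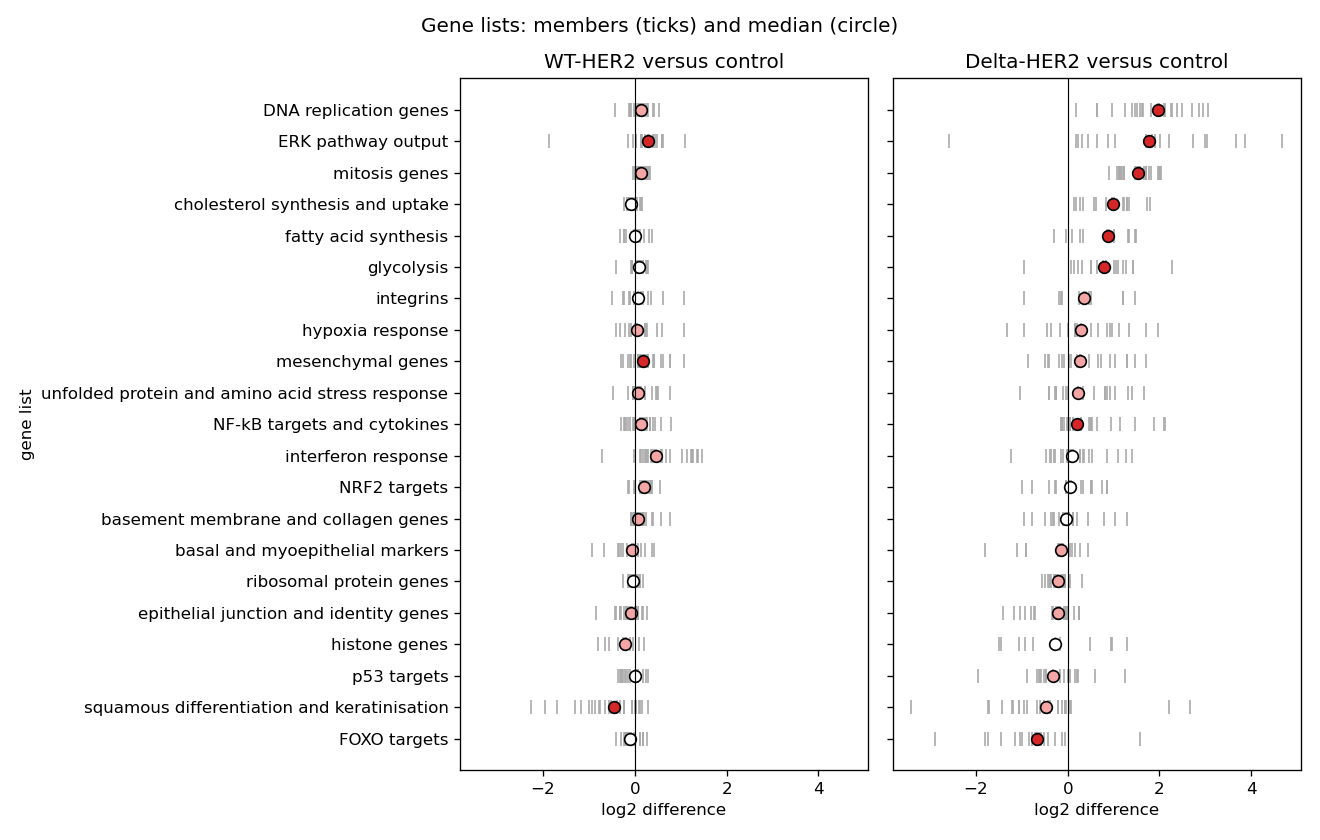
Log2 difference from control of each measured member (gray ticks) and the median (circles) of the 21 gene lists that passed camera in either comparison with control; red circles passed with an estimated correlation too, pink circles with the preset correlation alone, white circles with neither. The median of the DNA replication genes was 0.14 with WT-HER2 and 1.96 with Delta-HER2, and that of the interferon response genes was 0.46 and 0.10.

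The direct comparison of the HER2 forms asks where cells with the splice variant differed from cells with the full-length receptor, at ERBB2 levels that differed 1.97-fold. Cell cycle, metabolic and ERK pathway genes were higher with Delta-HER2, and FOXO targets were lower. Of 27 interferon response genes 12 were lower, although that list did not pass with an estimated correlation (adjusted p = 0.234). S100A8 was 20.56-fold higher than with WT-HER2 (log2 difference 4.36, SE 0.16, adjusted p = 4.89e-07), DUSP6 18.67-fold higher (4.22, SE 0.12, adjusted p = 1.68e-07) and FGFBP1, which encodes a carrier of fibroblast growth factors, 14.01-fold higher (3.81, SE 0.08, adjusted p = 6.43e-08). CYP3A4 differed by −5.35 (SE 0.23, adjusted p = 8.81e-07) and GPNMB by −4.02 (SE 0.12), both lower with Delta-HER2; the CYP3A4 level with Delta-HER2 (2.03) was within the background range, so the size of its difference is uncertain.

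In the direct comparison, 14 of 20 ERK pathway output genes were higher and 1, EPHA4, was lower with Delta-HER2 (16 and 1 adjusted over the list alone; median 1.12, camera adjusted p = 1.98e-15, and adjusted p = 0.0107 with an estimated correlation). All 24 mitosis genes were higher, over all genes and adjusted over the list alone (median 1.29, adjusted p = 0.0419 with an estimated correlation), as were 23 of 25 DNA replication genes, again on both counts (median 1.86, adjusted p = 0.0118 with an estimated correlation). MCM6 was 7.89-fold and CCNB1 2.86-fold higher. Of 16 cholesterol genes 14 were higher (16 adjusted over the list alone; median 1.00, adjusted p = 0.0177 with an estimated correlation), with HMGCS1 3.93-fold higher. Of 12 fatty acid synthesis genes 8 were higher (9 adjusted over the list alone; median 0.86, adjusted p = 0.0200 with an estimated correlation), and of 18 glycolysis genes 13 were higher and 1 was lower (14 and 1 adjusted over the list alone; median 0.70, adjusted p = 0.0185 with an estimated correlation). Of 21 FOXO targets 17 were lower and 1 was higher (19 and 1 adjusted over the list alone; median −0.63, adjusted p = 0.0185 with an estimated correlation), and PDK4 differed by −2.78 (SE 0.09).

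Interferon response genes were lower with Delta-HER2 than with WT-HER2 for 12 of 27 members and higher for 0 (13 and 0 adjusted over the list alone). Their median was −0.40, with camera adjusted p = 3.89e-05 but adjusted p = 0.234 with an estimated correlation. IFIT2 was 2.83-fold lower (SE 0.21 log2, adjusted p = 7.23e-04), and the differences were −1.35 for IFIT1 (SE 0.19), −0.95 for IFIT3 (SE 0.13) and −0.70 for IRF9 (SE 0.07). Of 26 NF-kB targets and cytokines 10 were higher and 4 lower, over all genes and adjusted over the list alone (adjusted p = 0.142 with an estimated correlation), with CXCL8 5.06-fold and CXCL1 2.75-fold higher. Of 23 epithelial junction genes 6 were lower and 2 higher (7 and 2 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), with the junction protein gene TJP3 2.69-fold lower. Of 19 p53 targets 8 were lower and 2 higher, over all genes and adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Of 25 ribosomal protein genes 4 were lower, over all genes and adjusted over the list alone (adjusted p = 0.368 with an estimated correlation). Of these calls, that of the junction genes was lost without WT-HER2 replicate 1 (adjusted p = 0.0621), WT-HER2 replicate 2 (0.0618) or Delta-HER2 replicate 2 (0.0608), and that of the p53 targets without the same arrays (0.0806, 0.0618 and 0.0608). The NF-kB call was lost without WT-HER2 replicate 3 (0.0810) or Delta-HER2 replicate 2 (0.0673), and the ribosomal call without WT-HER2 replicate 2 (0.0617).

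Other genes with large differences between the HER2 forms included the alcohol dehydrogenase gene ADH1B (−3.24, SE 0.12, with a background level in Delta-HER2 cells), CLCA4 (−2.96, SE 0.15), KLHDC8B (−2.56, SE 0.11) and CPM (−2.45, SE 0.15). In all, 4191 of 18404 genes (22.8%) passed limma, 2470 higher and 1721 lower with Delta-HER2, and 781 of them differed at least 2-fold. The balance moved with scaling, to 2640 and 1233 with median centring and to 2386 and 2058 with quantile normalization. The arrays of the groups did not overlap for 6378 genes (34.7%, against 10% by chance). ERBB3 was lower by −0.85 (SE 0.07, adjusted p = 2.65e-05) and EGFR by −0.30 (adjusted p = 0.0301). EGFR did not pass without WT-HER2 replicate 1 or 2 or any single Delta-HER2 array (adjusted p from 0.0598 to 0.0975). The other 20 lists did not pass, with camera adjusted p from 0.0761 to 0.890, among them fibroblast (median −0.10), blood and immune (−0.16) and endothelial markers (−0.03). Median, mean and test differed in sign for squamous differentiation genes, YAP targets, matrix proteases and inhibitors, histone genes and endothelial markers.

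How far the responses to the HER2 forms overlapped was read from the genes that changed against control in each. There were 272 genes called in both comparisons, of which 102 were higher in both and 146 lower in both, against 19.5 and 19.5 for the product of the call rates. That product is not the value for unrelated responses, because the comparisons share their control arrays. VCAN rose and KRT10 and GPNMB fell in both. For 217 of the 272 genes the difference was larger in Delta-HER2 cells, and 180 of them also differed between the HER2 forms. The remaining 24 genes changed in opposite directions. S100A8, S100A9 and FGFBP1 (−0.50 and 3.31) were among 9 genes that fell with WT-HER2 and rose with Delta-HER2, and ADH1B (1.04 and −2.20), CPM (1.72 and −0.73) and CXCR4, a chemokine receptor gene (0.96 and −1.03), were among 15 that did the reverse. With single arrays left out, the count of 272 was 124 without control replicate 2, 116 without control replicate 3, and 136 and 141 without WT-HER2 replicates 1 and 2. The count of 24 was 15, 9 and 6 without control replicates 1, 2 and 3, 13 and 14 without WT-HER2 replicates 1 and 2, and 14 and 11 without Delta-HER2 replicates 1 and 3. Other settings raised both counts, to 635 and 65 with array weights and to 512 and 60 with the olfactory receptor covariate.

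Of the genes called with Delta-HER2 and not with WT-HER2 (4397), 3376 also differed between the HER2 forms, among them DUSP6 and MCM6. With WT-HER2 alone 37 genes were called. An F test across the groups found 4499 genes, for 93.4% of which the difference from control was larger in Delta-HER2 cells (median size 0.61 log2, against 0.14 in WT-HER2 cells). Across all genes the differences from control correlated at r = 0.38 over genes, which are not independent replicates. In 100 simulations with no effects the shared controls alone gave a mean r of 0.50 (0.49 to 0.51), the covariance of the differences was 0.03 against 0.01 simulated, and 61.4% of genes had the same sign in both against 66.7% simulated, so neither r nor the share of signs by itself measures a shared response.

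**Figure D3:**
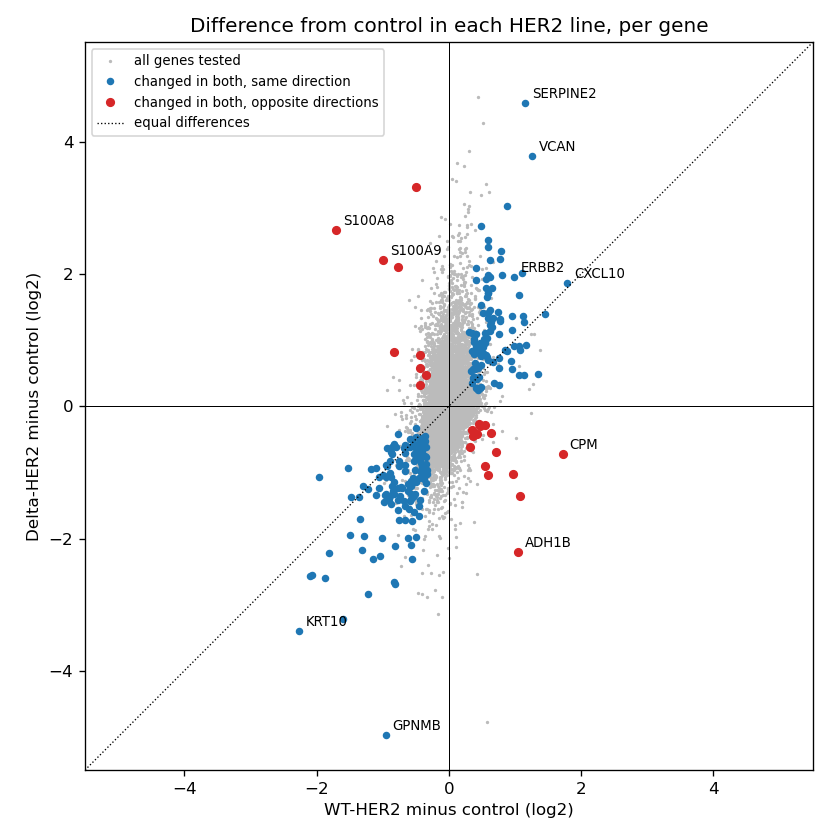
Difference from control of each gene in WT-HER2 cells (horizontal axis, log2) and in Delta-HER2 cells (vertical axis, log2), with gray points for all 18404 genes tested, blue for genes changed in the same direction in both and red for the 24 changed in opposite directions; the dotted line marks equal differences. Most blue points lie farther from 0 on the vertical than on the horizontal axis, and S100A8 stands at −1.71 and 2.66.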

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

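The test on small nucleolar RNA genes, the leaving out of 2 or 3 arrays together and the picking of single genes and probes for mention were chosen after the results were seen. The patterns weighed below were drawn from the results, and some of their tests name the arrays that stand apart. The tests and bounds for these patterns therefore do not count as set before the results were seen. The remaining tests in this part were set before.

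A difference between groups drew attention to 24 genes that were called in opposite directions against control in WT-HER2 and Delta-HER2 cells, 8.82% of the 272 genes called in both. All 24 differed in the direct test between the HER2 forms, but the selection fixed that outcome. Opposite differences add up in that test while the SE stays the same, so it lends the opposite calls no further weight. Among them, 9 fell with WT-HER2 and rose with Delta-HER2: CEMIP2, FGFBP1, LSG1, MTOR, NR2C2AP, S100A8, S100A9, SERPINB3 and SNORD14C. For SERPINB3 the levels in control (3.11) and WT-HER2 cells (2.34) lay within the background range. The 15 others rose with WT-HER2 and fell with Delta-HER2: ADH1B, AKAP12, ALDH3B1, CCBE1, CPM, CXCR4, GALNT15, IRF9, LYPD3, PC, REPS2, SORBS2, TMEM37, TMEM40 and TWIST1. Single arrays moved the count, to 15, 9 and 6 without control replicates 1, 2 and 3, to 13 and 14 without WT-HER2 replicates 1 and 2, and to 14 and 11 without Delta-HER2 replicates 1 and 3.

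A signal in data outside the comparisons came from the 13163 probes without a single gene symbol. Of these, 1132 differed between Delta-HER2 and control cells (507 higher and 625 lower), or 8.60%, against 21.9% of probes with 1 symbol. Between WT-HER2 and control cells 33 differed, and between the HER2 forms 1018. Probe 8095744 rose by 3.61 log2 with Delta-HER2 (adjusted p = 8.94e-07), probe 8104129 fell by 3.06 log2 (adjusted p = 2.97e-05), and probe 7893071 rose by 3.35 log2 with WT-HER2 and by 2.93 log2 with Delta-HER2. Of the 13163 probes 11775 were not listed and 1388 listed several symbols. No biological explanation was tested for them.

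The first pattern weighed is that control replicate 1, WT-HER2 replicate 3 and, less, Delta-HER2 replicate 2 deviated from their groups in the same direction across genes. The tests used control replicate 1 and WT-HER2 replicate 3, and a narrower signal range explained a mean share (R squared) of 0.121 of their deviation, with negative slopes, against 0.045 on Delta-HER2 replicate 2; the bounds were 0.1 to exclude it and 0.5 to accept it. Lower recovery of small RNAs predicted lower small nucleolar RNA genes, and these lay −0.018 and −0.055 from protein-coding genes on the 2 arrays tested. A different growth state predicted shifts of mitosis genes or FOXO targets over 0.3, and the largest was 0.117 in size on those 2 arrays, with −0.132 for mitosis genes on Delta-HER2 replicate 2. None of these explanations was accepted or excluded. Each value, over the 2 arrays tested or on 1 of them, fell between the bound set to exclude the explanation and that to accept it.

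The second pattern is that interferon response genes were higher in WT-HER2 than in control cells, a list call that was lost with an estimated correlation (adjusted p = 0.0586). The arrays that stand apart did not make it: without both, the median difference was 1.182 of its value with all arrays (0.55 against 0.46), and 14 of 27 members were higher. A response on a single array is argued against as well, since 3 of the 3 WT-HER2 arrays had list means (5.72 to 6.08) above the highest control array (5.39), and the Delta-HER2 arrays lay between (5.42 to 5.53). A response in 1 WT-HER2 culture stays open, because the labels do not say that the arrays came from separate cultures, and so do infection, the making of the line and an effect of the receptor, none of which was tested.

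The third pattern is that more genes changed in Delta-HER2 than in WT-HER2 cells, while the ERBB2 level was higher in Delta-HER2 cells too. A response of fixed shape that scales with the ERBB2 level left 1805 genes departing at scale 2. Over scales from 0.5 to 10 the lowest count was 226, at scale 8.5, between the bounds set. The error of the scaled WT-HER2 difference grows with the scale, so low counts at high scales cannot show how well such a response holds. A response of fixed shape does forbid genes that go opposite ways, and 24 did. For AKAP12, CPM, LSG1, LYPD3, MTOR, S100A9, SORBS2, TMEM37 and TMEM40 among them, 2 control values were equal to 3 decimals. Equal values enter the spread, so the p-values of these genes may be too small. A steady rise or fall of each gene with the ERBB2 level is argued against for those 24 genes alone, where at least 15 had been set as the bound: all 24 kept both signs without the 2 or 3 arrays that stand apart, but 12 and 9 were still called, and single arrays left out took the count under 15 (9 and 6 without control replicates 2 and 3, 13 and 14 without WT-HER2 replicates 1 and 2, 14 and 11 without Delta-HER2 replicates 1 and 3). For all other genes the level and the form of HER2 cannot be told apart, because 0 ERBB2 levels were seen with more than 1 transgene.

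Other splits of the same arrays into groups of 3 were compared with the real one. Of 10 splits 1, the real one, gave as many genes or lists in every contrast, and 10 splits are too few for a share under 0.05. The real counts of genes and the highest of the other splits were 309 and 0 for WT-HER2 against control, 4669 and 0 for Delta-HER2 against control, and 4191 and 0 between the HER2 forms. For lists they were 14 and 6, 17 and 11, and 12 and 10. The medians over the other splits were 1, 9 and 8 lists in the same order. For the F test, 2 of 100 splits drawn from 280 gave as many genes as the real 4499, a share under 0.05. That share rests on the Delta-HER2 arrays, which few drawn splits kept together, and shows only that they stand apart. It does not bear on how control and WT-HER2 arrays were assigned, so chance is not excluded for the 3 groups. The highest other split, with 4714, kept the Delta-HER2 arrays together and put control replicate 1 with WT-HER2 replicates 1 and 3, which points to a structure of the samples: 4 splits drawn kept the Delta-HER2 arrays together and gave at least 3498 genes, and the others gave at most 35.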

How the results depend on the processing

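Leaving out 2 or 3 arrays together and the olfactory receptor covariate were chosen after the results were seen; the other alternatives were set before. The ERBB2 differences kept their direction and their calls under every alternative (0.94 to 1.04, 1.92 to 2.01 and 0.91 to 1.03 log2). Of 337 calls of named genes 286 were never lost, and of 43 list calls 18 were never lost; no called gene or list reversed. Uncalled lists passed in 34 cases and uncalled named genes in 71.

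For WT-HER2 against control the 309 genes became 736 with array weights, 606 with the olfactory receptor median as a covariate and 134 with only the 2 groups compared, and the cause was not tested. Genes called in both comparisons (272) became 635 and 512 with array weights and the covariate, and those in opposite directions (24) became 65 and 60, 15 with median centring and 14 with all probes; the cause was not tested. With differences of at least 2-fold required, the counts were 47, 961 and 781 genes in the order WT-HER2 and Delta-HER2 against control and Delta-HER2 against WT-HER2, 976 in the F test, 33 called in both and 3 in opposite directions. At adjusted p below 0.01 the counts were 115 for WT-HER2 against control, 2772 between the HER2 forms, 107 in both and 7 in opposite directions. These thresholds are stricter by construction. With the replicate number as a block, the counts were 139 for WT-HER2 against control, 129 in both and 9 in opposite directions; the numbers do not pair the samples, as same-number deviations correlated at −0.508 to 0.302.

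The correlation of the responses across genes (0.377) was 0.432 with array weights, 0.455 with 2 arrays left out and 0.436 with 3 left out; the cause was not tested. List calls fell with an estimated correlation to 3, 8 and 7 in that order of contrasts, and for Delta-HER2 against control to 11 with genes above the median level, where fewer genes were tested. Fry, which does not compare a list with other genes, called 26 lists between the HER2 forms, and it reversed the direction of the uncalled ERBB receptor list with Delta-HER2 (median −0.238, adjusted p = 0.0106).

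With single arrays left out, where fewer samples remain, the ranges were 126 to 279 genes for WT-HER2 against control, 3805 to 5097 for Delta-HER2 against control, 3328 to 4381 between the HER2 forms, 3518 to 4764 in the F test, 116 to 254 in both and 6 to 19 in opposite directions. The correlation ranged from 0.318 to 0.420. Lists ranged from 10 to 15 for WT-HER2 against control, stayed at 17 for Delta-HER2 and ranged from 9 to 12 between the HER2 forms. With 2 arrays left out, 215 of the 309 genes, 4415 of the 4669 and 3866 of the 4191 were called again. Among list counts over all genes, the covariate also raised those of the interferon response (11 to 17), NF-kB (3 to 5) and NRF2 lists (2 to 4) higher with WT-HER2, of p53 targets higher with Delta-HER2 (2 to 4) and of ribosomal protein genes lower than with WT-HER2 (4 to 8, and 8 with 3 arrays left out). Of the genes that differed between the HER2 forms, 58.9% were higher with Delta-HER2, 68.2% with median centring and 53.7% with quantile normalization. Signal over background limits 4733 genes whose group means all lay under the olfactory receptor bound, and 47.2% of probes had identical values on at least 2 arrays.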

Other observations

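Both hypotheses and the gene families in this part were chosen after the results were seen, though the tests of the hypotheses were fixed before they were run.

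Since GPNMB fell most with Delta-HER2, lysosomal genes may be lower as a group. In a list of 30 measured genes 17 were lower and 3 higher, and without GPNMB the median was −0.36 log2 and camera with an estimated correlation gave 0.03943 as its p-value. CTSF fell by 1.28 log2, CTSK by 1.14 and PSAP by 0.67. Between the HER2 forms the value was 0.03538 and for WT-HER2 against control 0.8548. The idea was raised and tested on the same data, so it stays a hypothesis.

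Since DNA replication and mitosis genes rose with Delta-HER2, ribosome biogenesis genes may be higher too. Of 26 measured genes 23 were higher and 0 lower, with a median of 1.11 log2, and camera with an estimated correlation gave 0.01838 as its p-value. NOP2 rose by 1.48 log2, DDX21 by 1.61 and NIP7 by 1.13. Between the HER2 forms the value was 0.01357 and for WT-HER2 against control 0.524, where 0 of 26 genes passed.

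Among 7 gene families, none passed camera with an estimated correlation, adjusted over families and contrasts (lowest adjusted p = 0.104). With Delta-HER2 against control, 15 of 20 nucleoporin genes rose and 0 fell (median 0.68 log2), 11 of 16 aminoacyl-tRNA synthetase genes rose and 1 fell (0.59), 6 of 8 RNA polymerase I subunit genes rose and 1 fell (0.73), 28 of 69 histone genes rose and 8 fell (0.20), whereas of the 11 histone genes listed beforehand 4 rose and 5 fell (−0.27, camera adjusted p = 0.504), and 75 of 439 numbered zinc finger genes fell and 10 rose (−0.13). Metallothionein genes rose in 4 of 10 cases with Delta-HER2 (0.20) and in 3 of 10 with WT-HER2 (0.33), and 5 of 20 S100 genes rose and 3 fell with Delta-HER2 (0.09). These medians kept their sign with quantile normalization and with median centring. With WT-HER2, 1 of the 69 histone genes rose and 0 fell (−0.002). Histone genes are alike in sequence, and probes can take up signal from several of them.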
